A study of Danio rerio with 6 samples.

How the data were processed

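Messenger RNA abundance was measured by RNA sequencing in the livers of wild-type (WT) zebrafish and of zebrafish in which scd had been knocked out with CRISPR-Cas9. The series holds 6 libraries, 3 from WT fish and 3 from mutants. Per the labels' protocols, they were made from total RNA of liver, from fish kept at a water temperature of 28 °C. Sex, age, clutch, feeding state and sampling date are not given in the sources used here, nor is whether each library came from 1 fish or from a pool. The p-values therefore measure only the spread between these samples, which may be technical in part.

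The authors deposited 1 table of whole-number read counts per gene, with no normalization. Per the submitters' processing notes, the tools were Trimmomatic 0.36, STAR 2.7 and featureCounts 1.5.2, and the genome build was GRCz11. Whether counting used strand, and how reads that align to several places were treated, is not given in the sources used here. Counts of near-identical gene copies, such as the vitellogenin, class I histocompatibility, trypsin and haemoglobin families, and of overlapping or antisense genes are therefore uncertain. The table names genes by symbol only. Of its 30955 rows, 1 has no gene name. This row holds between 0.568% and 1.02% of a library's counts and was kept out of library sizes and tests, which leaves 30954 genes. All 6 columns of counts were matched to a sample by name.

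The counts were tested as deposited with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the group, which left 12889 genes. Library sizes were scaled by the trimmed mean of M-values (TMM), and the quasi-likelihood test with robust dispersion compared mutant with WT. Fold changes are mutant over WT on the log2 scale, with the standard error taken as the size of the change divided by the square root of F. P-values were adjusted by the Benjamini-Hochberg method, and an adjusted p under 0.05 was called. Levels are TMM-scaled counts per 1e6 counts (CPM) unless stated. For a gene with no count in a group, the fold is a lower bound against a floor of 3 counts over the group, and with 1 to 3 counts it is the ratio of summed counts over scaled library sizes with its exact 95% counting interval. These bounds and intervals cover counting error only.

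The gene lists, the tests, the rule for naming genes and the alternatives were fixed before the data were examined, apart from those said to be chosen afterwards. The lists cover liver metabolism, stress and signalling, and markers of other cell types. They hold 1180 symbols, of which 1103 are in the table and 938 passed the filter. The 37 lists with at least 5 measured members were tested with camera (limma 3.58.1) on edgeR's log2 CPM with a prior count of 2 and a preset correlation of 0.01, beside camera with an estimated correlation and fry. The lymphocyte list had 3 measured members and was not tested. For each list, member genes were also adjusted over the list alone. Vitellogenin was summed over vtg1 to vtg7, and exocrine pancreas over its list, as CPM of the total named counts, and compared by an exact two-sided permutation test on log2(CPM + 1). With 3 libraries against 3, the smallest p this test can give is 0.1. Similarity between libraries was described by Spearman's correlation over all filtered genes and by principal components of the 1000 most variable genes.

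The genes named are scd and scdb, then the 10 called genes with the largest rises and the 10 with the largest falls among those with a mean log2 CPM above 1 and no overlap between the groups' CPM. From each list the rule adds up to 3 called members, or, where none was called, the member with the highest mean level. Other genes named were chosen after their values were seen. Gene order was taken from the RefSeq annotation of assembly GRCz12tu, another build, and used only to ask which genes neighbour each other.

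Named counts per library lay between 22525300 and 25853000, to 6 significant digits. Vitellogenin transcripts took up to 57.3% of them, so the counts left for other genes ranged from 9756360 to 23774400. On simulated counts with the estimated dispersions, over 12399 genes, the test recovered 0% of genes changed 2-fold, 30% of those changed 4-fold, 84% of those changed 16-fold and 98% of those changed 64-fold, with 11 false calls among 117. With 0.1 of the dispersion, over 12677 genes, these shares were 86%, 96%, 96% and 100%, with 20 false calls among 209. The false share was above the nominal 5% in both simulations.

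The alternatives were DESeq2 size factors, upper-quartile factors, total counts, no filter beyond 1 count, a filter of 1 CPM in 3 libraries, the replicate number as a block, library sizes without vitellogenin and pancreas genes, each library left out in turn, a non-robust dispersion, the DESeq2 1.42.0 Wald test, limma-voom, a minimum change of 2-fold, and other set tests. A covariate for oocyte transcripts, with 6 and with 5 libraries, was added after the data were examined, as were library sizes from the counts outside vitellogenin without scaling factors, used for the cholesterol genes only. Pairs of libraries of a group differed by 76.6 to 1574 chi-square units per degree of freedom over genes with at least 20 counts, which is more than counting error gives for a repeated library.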

Results

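The data are gene counts from 6 zebrafish liver libraries, 3 labelled WT and 3 labelled scd mutant. The comparison asks how liver gene expression differs when scd is knocked out. The gene encodes stearoyl-CoA desaturase, the enzyme that makes monounsaturated from saturated fatty acyl-CoA. Total counts, with the row that names no gene, were 22736924, 25546642 and 25001005 in WT replicates 1 to 3 and 26021730, 22971108 and 24028725 in mutant replicates 1 to 3.

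The scd transcript was not lower in the libraries labelled mutant. Its level was 30.3, 18.1 and 431 CPM in WT replicates 1, 2 and 3 (159.7 ± 234.8, mean and SD, n = 3). It was 693, 111 and 56.7 CPM in mutant replicates 1, 2 and 3 (286.7 ± 352.7, n = 3). The log2 fold change was 0.84 with a standard error of 1.44 (edgeR quasi-likelihood test, adjusted p = 0.786). Without mutant replicate 1 it turned to -0.95 (adjusted p = 0.702). The counts do not show the edited sequence, and a knockout that shifts the reading frame need not lower its transcript, so the level does not check the labels. The paralogue scdb had 2 counts over the WT libraries and 12 over the mutant ones, a ratio of 3.13 with a counting interval of 0.696 to 28.8.

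The libraries differed in more than genotype. Vitellogenin transcripts, which encode the egg yolk precursor that the liver of egg-laying females secretes, made up 44.1%, 51.0% and 49.8% of counts in WT replicates 1 to 3. They made up 57.3% and 57.3% in mutant replicates 1 and 2, and 0.0433% in mutant replicate 3. The group values were 48.3% ± 3.68 and 38.2% ± 33.0 (SD, n = 3 each), with an exact permutation p = 1. Without mutant replicate 3 the log2 difference turned from -3.21 to 0.25. Erythrocyte transcripts summed to 7257 CPM in mutant replicate 3 and to between 203 and 299 CPM in the other 5 libraries. Gonad and oocyte transcripts summed to 161 and 158 CPM in WT replicates 1 and 2 and 177 CPM in mutant replicate 1, against 4.75 CPM in WT replicate 3 and 3.06 and 4.37 CPM in mutant replicates 2 and 3. The zona pellucida gene zp2.2 stood at 27.3, 36.3 and 64.5 CPM in the libraries that held them and at 0.0562, 0.0412 and 0 CPM in WT replicate 3 and mutant replicates 2 and 3. Exocrine pancreas transcripts made up 0.1595% ± 0.1201 of WT counts and 0.125% ± 0.118 of mutant counts (SD, n = 3 each, exact permutation p = 1), with a range from 0.0222% in WT replicate 1 to 0.261% in mutant replicate 3.

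**Figure D1:**
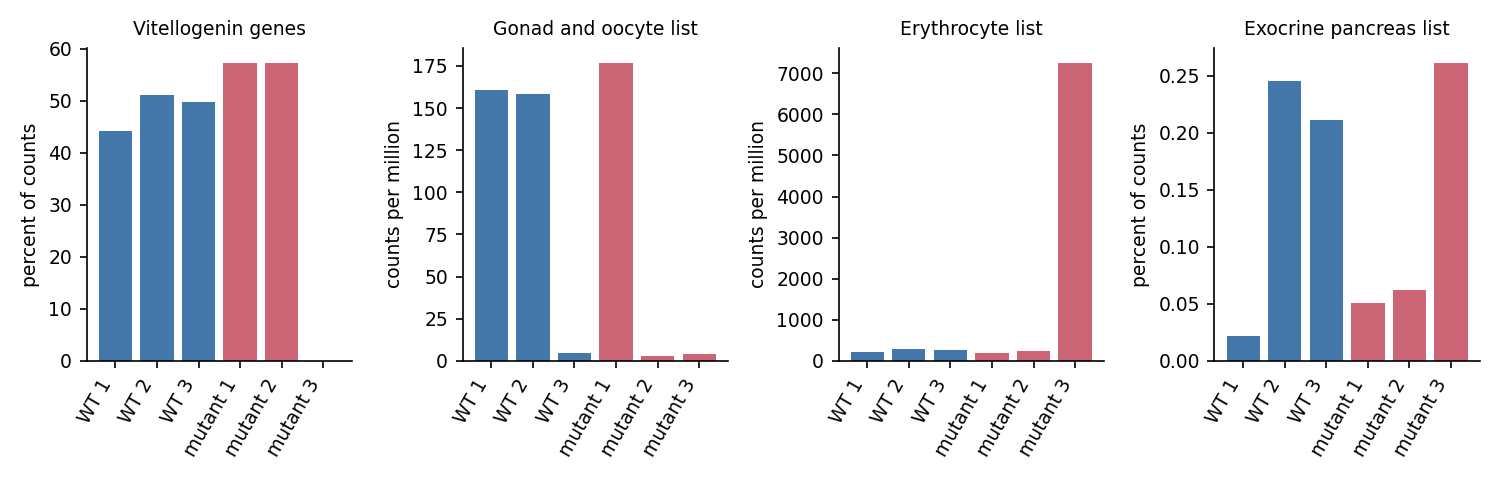
Share or level of marker transcripts in each library, with vitellogenin and exocrine pancreas in percent of counts and the gonad and erythrocyte lists in CPM (bars are single libraries, WT in blue and mutant in red). Vitellogenin stands at 0.0433% in mutant 3 and between 44.1% and 57.3% in the others.

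Spearman correlations between libraries averaged 0.883 within genotypes and 0.834 between them, and the ranges overlapped (0.816 to 0.944 and 0.762 to 0.908). The first principal component held 55.1% of the variance of the 1000 most variable genes. It set WT replicates 1 and 2 and mutant replicate 1, which carried oocyte transcripts, apart from the other libraries. Genotype accounted for 32.6% of the variance in these genes, and the division by oocyte transcripts for 52.2%.

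Between the genotypes, 31 of 12889 genes changed, 15 rising and 16 falling in the libraries labelled mutant (edgeR quasi-likelihood test, adjusted p under 0.05). Among the falls were ulk1a, nr1d2a, cyp24a1 and fabp2, and among the rises mhc1uba, cyp2x9, rdh12 and acot11b. The autophagy-initiating kinase ulk1a fell from 35.77 ± 10.05 to 1.09 ± 0.341 CPM (SD, n = 3 each), a log2 fold change of -5.05 ± 0.40 (SE, adjusted p = 0.0118). The clock repressor nr1d2a fell from 240.0 ± 41.9 to 26.6 ± 5.81 CPM, a change of -3.17 ± 0.35 (adjusted p = 0.0284). The enzyme that inactivates vitamin D hormone, cyp24a1, stood at 295, 388 and 1627 CPM in WT replicates 1 to 3 and between 0.242 and 0.797 CPM in the mutant ones (log2 fold change -10.84 ± 1.16, adjusted p = 0.0284).

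The fall of the largest size was that of zgc:171534, with 5624 counts over the WT libraries and 1 over the mutant ones. Its ratio of 10792 had a counting interval from 1936 to 426351 (adjusted p = 0.00239). The zinc finger gene znf1179 fell from 58.1 ± 8.90 to 0.873 ± 0.174 CPM (log2 fold change -6.03 ± 0.33, adjusted p = 0.00239). The peptide cyclase gene qpct changed by -7.42 and zgc:174862 by -5.69 on the log2 scale. The transport and lipid-binding gene fabp2, an intestinal fatty acid-binding protein, changed by -3.34. The remaining named falls were FP067424.1 at -4.31, si:ch211-195h23.3 at -3.66 and si:ch211-199g17.2 at -3.37. Adjusted p for these 6 genes lay between 0.0194 and 0.0440. The glucocorticoid-responsive transcription factor klf9 was also called, from 74.4 ± 14.5 to 17.7 ± 1.99 CPM (log2 fold change -2.07, adjusted p = 0.0471). It falls outside the naming rule and was chosen after its value was seen.

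Of the rises, rpgrip1 had no count in WT and 441 counts in mutant libraries, which makes it at least 76.6-fold higher (adjusted p = 0.0284). The class I histocompatibility gene mhc1uba rose from 2.02 ± 1.15 to 317 ± 155 CPM (log2 fold change 7.29 ± 0.74, adjusted p = 0.0268), with the caution that reads may be shared with related copies. The cytochrome P450 gene cyp2x9, the called member of the xenobiotic list, rose from 9.08 ± 0.283 to 75.9 ± 21.1 CPM (3.06 ± 0.30, adjusted p = 0.0268). The retinol dehydrogenase gene rdh12 rose from 7.09 ± 2.58 to 43.5 ± 1.96 CPM (2.62 ± 0.33, adjusted p = 0.0390). The acyl-CoA thioesterase gene acot11b changed by 4.43 and pm20d1.1, an enzyme of N-acyl amino acids, by 5.41 on the log2 scale, from mean WT levels of 0.206 and 0.102 CPM. The other named rises were CU570769.3 at 5.03, CABZ01079281.1 at 3.34 and paqr3b at 2.91. The gene si:ch211-133l5.7 had 1 count over the WT libraries, and the lower end of its counting interval was 72.6-fold. Adjusted p for these 6 genes lay between 0.0268 and 0.0440.

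**Figure D2:**
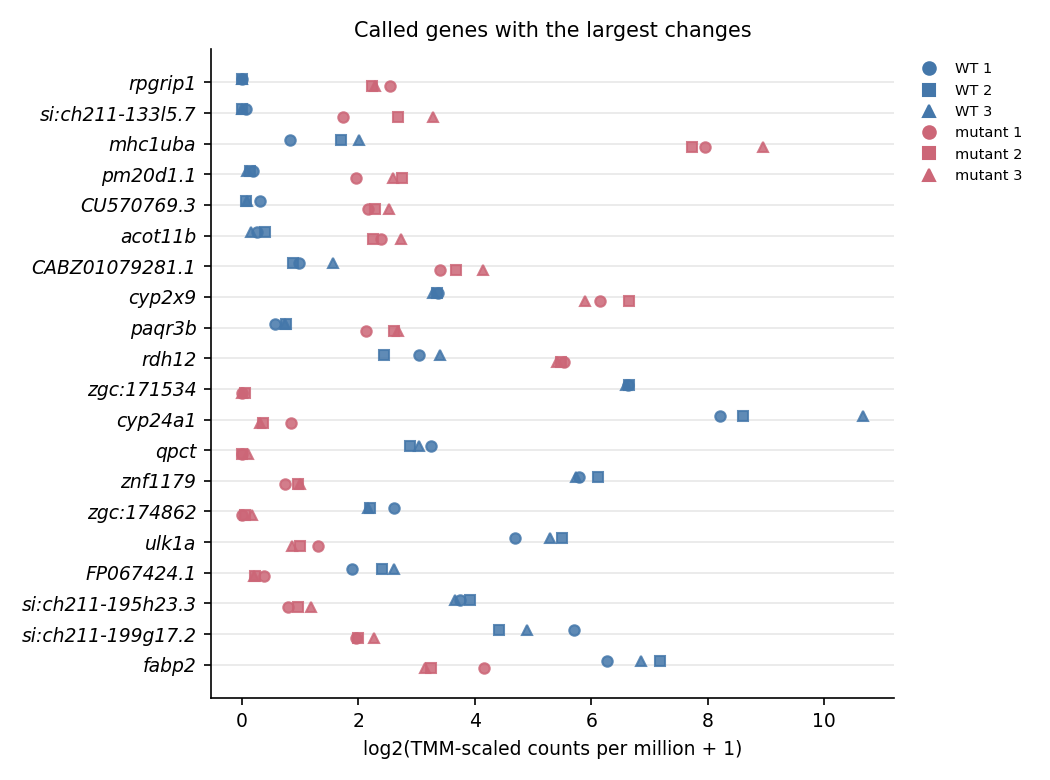
Levels of the 20 named genes with the largest called changes, as log2 of TMM-scaled CPM plus 1, with 1 point per library (WT in blue, mutant in red, symbol shapes for replicates 1 to 3). The upper 10 genes rose and the lower 10 fell, with no overlap between groups.

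The number of calls rested on each library. Without WT replicate 1, 2 or 3 it was 3, 5 and 5, without mutant replicate 1 it was 77, and without mutant replicate 2 it was 2. Without mutant replicate 3, the library lacking vitellogenin, it was 21 of 13027 genes, 12 higher and 9 lower, and 10 of these were called in all 6 libraries too. With total counts in place of TMM, the median of all genes shifted by 0.98 on the log2 scale and 394 genes were higher against 73 lower. The CPM of the groups did not overlap for 3589 genes, 27.8% of those tested, where a division of the libraries gives 10% on average. Genes vary together and the other divisions were not counted, so this excess alone does not show an effect of genotype.

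The genes of cholesterol synthesis stood together above their WT level in the libraries labelled mutant. The median log2 fold change of the 29 measured members was 2.52, and 25 of them had a positive value. The enzymes hmgcs1, fdps, sqlea, lss and hsd17b7 act in this order on the way from acetyl-CoA units to sterols, and their log2 fold changes were 5.85, 5.09, 8.32, 5.76 and 5.02. The level of hmgcs1 was 10.9, 7.96 and 18.3 CPM in WT replicates 1 to 3 and 547, 1472 and 126 CPM in mutant replicates 1 to 3 (adjusted p = 0.0683). That of sqlea was 0.0960, 0.314 and 0.843 CPM against 170.4, 222 and 4.98 CPM (adjusted p = 0.0943). The list was called by camera at the preset correlation (adjusted p = 4.64e-08), but not with an estimated correlation (adjusted p = 0.960) or by fry (adjusted p = 0.231). Over all genes, edgeR with TMM called 0 members in all 6 libraries, with 19 at an unadjusted p under 0.05 and a positive value and 1 with a negative one. It called 18 higher with total counts, under the shift of 0.98 in all genes, 7 without the filter and 1 with upper-quartile factors. With the oocyte covariate it called 0 in 6 libraries and 16 higher in 5. DESeq2's Wald test called 18 higher and 1 lower, hmgcs1 among them (adjusted p = 1.93e-11), and limma-voom 0. Adjusted over the list alone, 18 members rose and 1 fell. The low-density lipoprotein receptor ldlra was the one below WT, with 243, 633 and 698 CPM in WT and 145, 80.9 and 44.3 CPM in mutant libraries (log2 fold change -2.54, adjusted p = 0.112 over all genes and 0.00768 over the list alone). The other receptor gene of the list, ldlrb, was among the 18 that rose (edgeR, adjusted p = 0.0116 over the list alone). The regulator srebf2 had a log2 fold change of -0.06.

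Under TMM, mutant replicate 3, without vitellogenin and with high erythrocyte transcripts, lay between WT and the other mutant libraries for these genes. This position depends in part on scaling, since its TMM factor was 2.97, against 0.632 and 1.07 in mutant replicates 1 and 2. With total counts in all 6 libraries the list mean differed by 3.02 ± 0.35 (SE), where the median of all genes was itself 0.98. Under TMM the difference was 2.37 ± 0.73, where that median was 0.04. Without mutant replicate 3 the difference under TMM was 3.01 ± 0.37, where that median was -0.03. The list's median deviation from the WT mean was 2.98 and 3.19 in mutant replicates 1 and 2, 1.28 in mutant replicate 3, and -0.25, -0.28 and 0.56 in WT replicates 1 to 3. Without mutant replicate 3, 7 members rose over all genes. These were lss (6.22 ± 0.39), fdps (5.58 ± 0.32), hsd17b7 (5.47 ± 0.35), dhcr7 (3.63 ± 0.26), nsdhl (3.02 ± 0.25), hmgcs1 (6.33 ± 0.65) and sqlea (8.86 ± 0.83), as log2 fold changes with SE and adjusted p from 0.00636 to 0.0392 by edgeR. The 5-library list median was 2.85, with 20 members higher and 1 lower adjusted over the list alone. Adjusted p with an estimated correlation was then 0.855.

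**Figure D3:**
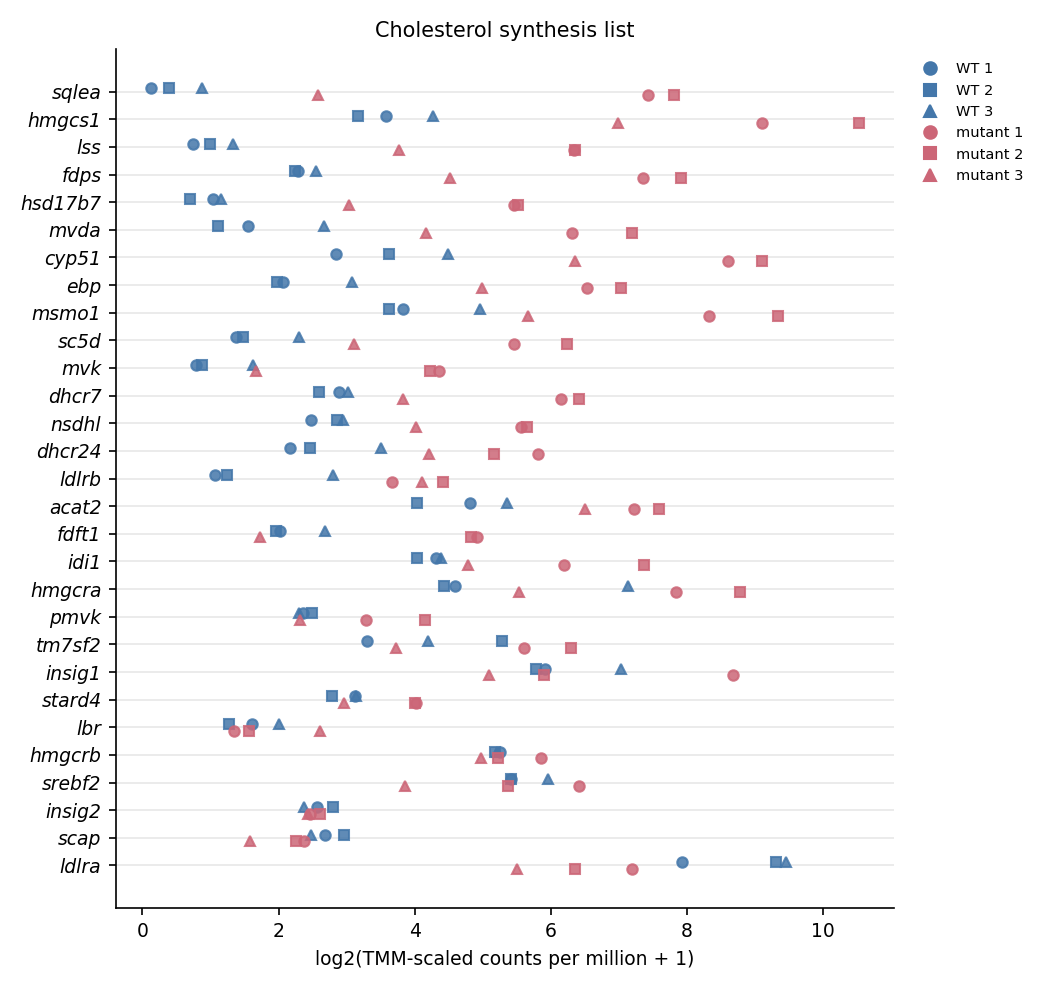
Levels of the 29 measured cholesterol synthesis genes as log2 of TMM-scaled CPM plus 1, with 1 point per library (WT in blue, mutant in red, symbol shapes for replicates 1 to 3), ordered by fold change. Mutant 3 lies nearer to WT than mutants 1 and 2 for most of the upper genes, and ldlra, at the bottom, lies lower in mutants.

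In the NADPH and pentose phosphate list, 10 of 13 measured members had a positive log2 fold change, with a median of 0.53. Camera at the preset correlation did not call the list (adjusted p = 0.0575), fry did (adjusted p = 0.0483, and 0.0528 without mutant replicate 3), and with an estimated correlation camera gave an adjusted p = 0.892. Camera at the preset correlation did call the list without mutant replicate 3 (adjusted p = 0.0431, and adjusted p = 0.855 with an estimated correlation), with upper-quartile factors (adjusted p = 0.0482), without the filter (adjusted p = 0.0294) and with the oocyte covariate in 6 and 5 libraries (adjusted p = 0.0478 and 0.0366). Adjusted over the list alone, 4 members rose, among them pgd. Over all genes, edgeR with TMM called 0 of the list's members, with 6 at an unadjusted p under 0.05 and a positive value and 1 with a negative one. Called higher were 4 with total counts, 1 without the filter, 1 with the filter of 1 CPM in 3 libraries, 1 with upper-quartile factors, 1 with a non-robust dispersion, 1 with the oocyte covariate in 5 libraries, 4 by DESeq2 and 1 by limma-voom. The level of pgd, a dehydrogenase of the pentose phosphate pathway, was 30.4, 40.1 and 36.4 CPM in WT and 150.7, 155.9 and 129.8 CPM in mutant libraries (log2 fold change 2.03, adjusted p = 0.0520). The fatty acid synthesis list, which covers the pathway scd belongs to, showed no common direction in all 6 libraries under TMM. Its median over 30 members was 0.11 and camera gave an adjusted p = 0.751. Without mutant replicate 3 the median was 0.26 (camera at the preset correlation, adjusted p = 0.138). There, 8 members were higher and 2 lower at an unadjusted p under 0.05. Over all genes, edgeR called 0 members with TMM and 3 higher and 0 lower with total counts. The shift of 0.98 in all genes under total counts bears on these calls and on those of the NADPH list. DESeq2 called 3 higher and 1 lower. The most abundant member, the desaturase fads2, had 1293, 1729 and 3237 CPM in WT and 5053, 1965 and 489 CPM in mutant libraries (log2 fold change 0.26, adjusted p = 0.892).

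The insulin signalling list lay below WT, with a median log2 fold change of -0.71 over 23 members. Camera at the preset correlation called it (adjusted p = 0.0346) and so did fry (adjusted p = 0.0483), but camera with an estimated correlation did not (adjusted p = 0.892). Adjusted over the list alone, 9 members fell and 3 rose. Over all genes, edgeR with TMM called 0 members in all 6 libraries, with 11 at an unadjusted p under 0.05 and a negative value and 3 with a positive one. It called 2 higher and 3 lower with total counts and 2 higher and 1 lower without the filter. With the oocyte covariate it called 0 higher and 2 lower, in 6 and in 5 libraries, and without mutant replicate 1 it called 0 higher and 1 lower. DESeq2 called 2 higher and 8 lower, and limma-voom 0. Levels in WT were highest in replicate 3 for the members named next, which were chosen after their values were seen, apart from igfbp1a. The adaptor irs2b stood at 4.85, 9.38 and 41.7 CPM in WT and 0.613, 0.700 and 1.08 CPM in mutant libraries, and the binding protein igfbp1b at 10.7, 21.0 and 165 CPM in WT and 1.23, 0.823 and 1.198 CPM in mutant ones. The most abundant member, igfbp1a, was at 11.3, 89.0 and 2560 CPM in WT and 9.01, 5.76 and 35.2 CPM in mutant libraries (adjusted p = 0.225). The list lost its call without mutant replicate 2 (adjusted p = 0.0556), without mutant replicate 3 (adjusted p = 0.0949), with the filter of 1 CPM in 3 libraries (adjusted p = 0.0580) and with the oocyte covariate in 5 libraries (adjusted p = 0.0509). With total counts its median turned to 0.30, under the shift of 0.98 in all genes, and camera still called it below.

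All 13 mitochondrially encoded genes and all 73 ribosomal and translation genes measured had negative log2 fold changes under TMM. The medians were -0.98 and -0.80, and camera at the preset correlation called both lists (adjusted p = 6.69e-07 and 5.04e-11). Neither held with an estimated correlation, which was 0.685 and 0.993 (adjusted p = 0.960 for each), and fry gave adjusted p = 0.102 and 0.728. The examples by level were mt-co1, at 9235, 7116 and 9382 CPM in WT and 6528, 4953 and 3959 CPM in mutant libraries, and rps2, at 5036, 5879 and 5639 CPM in WT and 6523, 2568 and 979 CPM in mutant ones. The ribosomal list stood at 0.09 from the WT mean in mutant replicate 1, at -1.10 in mutant replicate 2 and at -2.44 in mutant replicate 3. Its median was -0.41 without mutant replicate 3 and -1.64 without mutant replicate 1, where 70 members fell adjusted over the list alone (adjusted p = 0.844 with an estimated correlation). With total counts the mitochondrial median was -0.23 and the ribosomal one -0.46. As a share of counts, mitochondrially encoded transcripts made up 3.237% in mutant replicate 3, the highest of the 6 libraries. They made up 1.757% to 2.711% in WT libraries, and less than in any WT library in mutant replicates 1 and 2. Vitellogenin took 0.0433% of counts in mutant replicate 3 and 44.1% to 57.3% in the other libraries, which raises the share of all other transcripts there. The share therefore cannot show whether the low mitochondrial level of mutant replicate 3 under TMM comes from its scaling factor of 2.97. The signs of mt-co1 turned with total counts, to 0.03, under the shift of 0.98 in all genes. Over all genes, edgeR with TMM called 0 members of either list, with 6 mitochondrial and 0 ribosomal members at an unadjusted p under 0.05, limma-voom called 0, and DESeq2 called 7 mitochondrial members lower and 0 ribosomal ones.

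The inflammation and acute phase list was called below WT by camera at the preset correlation (median -0.39 over 37 members, adjusted p = 0.0346), but not with an estimated correlation (adjusted p = 0.960) or by fry (adjusted p = 0.741). Its call was lost without WT replicate 3 (adjusted p = 0.444), without mutant replicate 1 (adjusted p = 0.0504), without mutant replicate 2 (adjusted p = 0.295) and with the filter of 1 CPM in 3 libraries (adjusted p = 0.0592). With total counts its median turned to 0.57, under the same shift. The fibrinogen gene fga stood at 4114, 4366 and 6367 CPM in WT and 4536, 1971 and 3361 CPM in mutant libraries (adjusted p = 0.597).

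Every other division of the 6 libraries into 3 and 3 called more lists at the preset correlation, 9 to 17, than the 5 called for genotype. The other 32 of the 37 lists tested were not called by camera. Leaving out 1 library turned the median of 16 of them and brought a call at the preset correlation for 16, none of which held with an estimated correlation. Among the liver lists, hepatocyte markers had a median of -0.28 (tfa, transferrin, log2 fold change -0.61), lipoprotein genes -0.35 (apoa1b, 0.54), bile acid genes 0.10 (fabp10a, -0.30), glycolysis and gluconeogenesis -0.15, PPAR targets -0.81 (ucp1, -1.46) and mitochondrial fatty acid oxidation 0.10 (acadm, 0.12). Without mutant replicate 1, the hepatocyte, PPAR, glycolysis and lipoprotein lists were called below WT (adjusted p = 0.000612, 0.00284, 0.0108 and 0.0265, and adjusted p = 0.520 for each with an estimated correlation). In the lipid droplet list the phosphatidate phosphatase lpin1 was at 201, 468 and 837 CPM in WT and 96.8, 32.3 and 16.7 CPM in mutant libraries (log2 fold change -3.37, adjusted p = 0.115). The clock list held the called gene nr1d2a, and adjusted over the list alone 2 members fell and 1 rose. The stress lists had medians of 0.46 for heat shock (hsp90ab1, -1.18), 0.26 for the unfolded protein response (hspa5, 0.81), 0.07 for the integrated stress response (nupr1b, -0.91) and 0.19 for oxidative stress (cat, 0.20). Of the lists for other cell types, the erythrocyte median was 1.73 and turned to -0.30 without mutant replicate 3, which alone had high hbba1 (1219 CPM against 86.1 to 228 CPM). The list was called above WT without mutant replicate 2 (adjusted p = 0.00284, and adjusted p = 0.960 with an estimated correlation). The exocrine pancreas median was -1.40, and -1.97 without WT replicate 1, the library with the smallest share of these transcripts. The list was then called below WT (adjusted p = 4.63e-19, and adjusted p = 0.769 with an estimated correlation), and 22 members fell adjusted over the list alone. The immediate early median was -2.14, with junbb at 675 CPM in WT replicate 3 and 90.3 and 141 CPM in the other WT libraries. It turned to 0.80 without WT replicate 3 (adjusted p = 0.0985), and the list was called below WT without WT replicate 1 (adjusted p = 0.00329, and adjusted p = 0.921 with an estimated correlation). The gonad and oocyte list, at a median of -0.81, was called without WT replicate 3 (adjusted p = 2.15e-06, and adjusted p = 0.936 with an estimated correlation) and without mutant replicate 1 (adjusted p = 2.08e-05, and adjusted p = 0.844 with an estimated correlation). The biliary, endothelial, stellate, myeloid and interferon medians were 0.50, -0.36, 0.11, 0.15 and -0.43. Without mutant replicate 3 the biliary, stellate and myeloid medians turned to -0.25, -0.41 and -0.70, and the endothelial list was called below WT (adjusted p = 0.0431, and adjusted p = 0.855 with an estimated correlation). Without WT replicate 3 the interferon median turned to 1.92 and the list was called above WT by camera at the preset correlation (adjusted p = 1.798e-06, and adjusted p = 0.936 with an estimated correlation), where 12 members rose adjusted over the list alone. With 6 libraries the median and the direction camera gave differed in sign for the stellate and interferon lists. The same held for the intestine list (median 0.65) and the nuclear oxidative phosphorylation list (median 0.02).

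**Figure D4:**
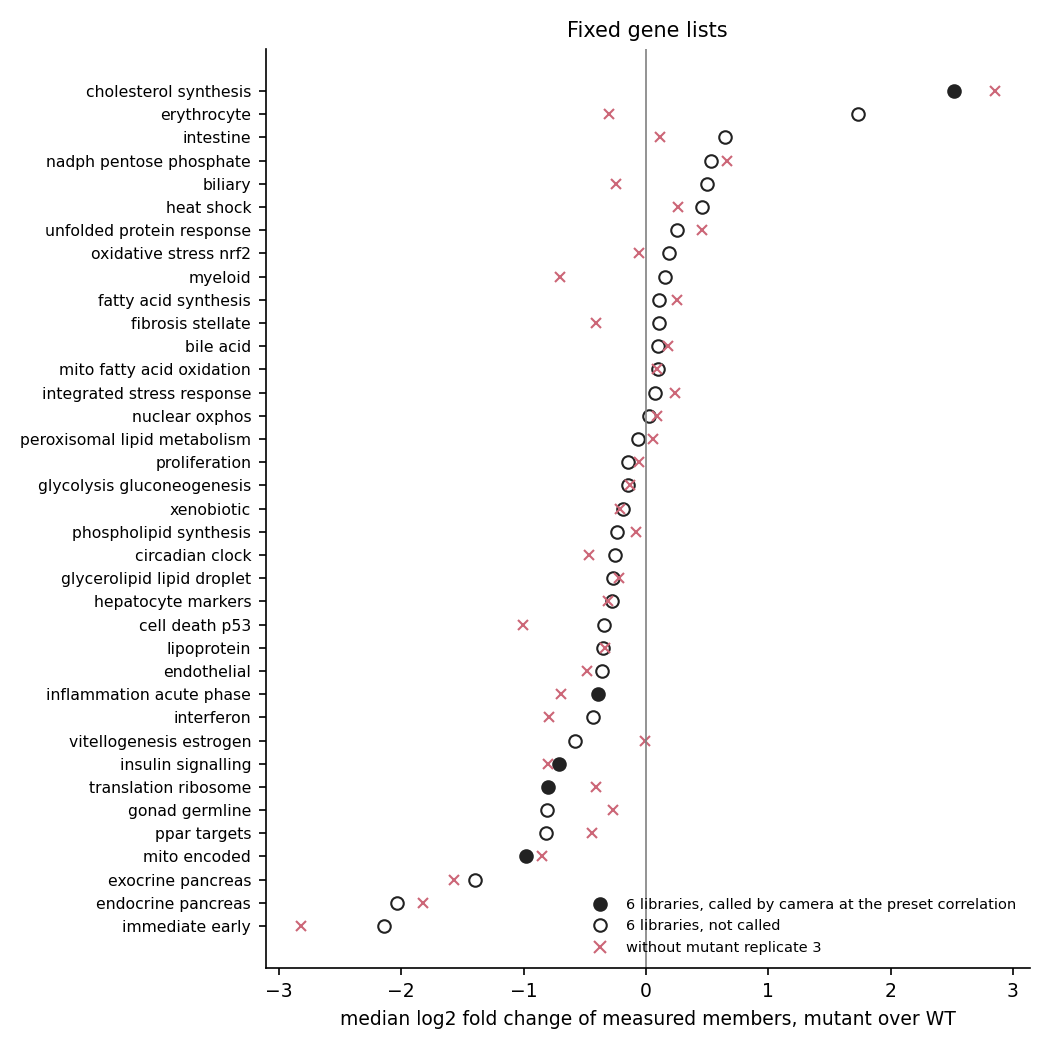
Median log2 fold change (mutant over WT) of the measured members of each of the 37 tested lists, with circles for 6 libraries, filled where camera at the preset correlation called the list, and crosses without mutant replicate 3. Cholesterol synthesis is at 2.52 and 2.85 and the immediate early list at -2.14 and -2.82.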

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

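The row of the table that names no gene was not used in any comparison and held up to 1.02% of a library's counts, in mutant replicate 3. What it counts is not stated in the sources used here. In the paragraphs that follow, the tests of dilution, of the oestrogen response, of the genes called without mutant replicate 3, of the WT state in that library, of its part in the cholesterol pattern, of ovarian carry-over, of vitellogenin's share of counts and of the size of the ratios were chosen only after the result was seen.

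Mutant replicate 3 lacked vitellogenin, at 0.0433% of counts. Dilution of liver RNA by another tissue is argued against, since hepatocyte markers, scaled without vitellogenin, had a median log2 ratio of 0.32 to the other 5 libraries (quartiles 0.05 and 1.02), where vitellogenin was at -10.22. A liver of the same origin as the WT libraries, with the mutant label, is argued against by a share of genes only. Of 24 genes on in 1 genotype and off in the other among the remaining 5 libraries, 8.33% were in the WT state in mutant replicate 3 (2 genes, interval 1.026% to 26.997%). A fish of the mutants' family without the mutation stays open, since it could share their other alleles and the counts do not show the edited sequence. In that library 62.5% of the 24 genes were in the mutant state (40.6% to 81.2%) and 7 in neither, and of the 21 genes called without it, 71.4% lay nearer to the mutant mean (47.8% to 88.7%). Both shares lay above the bound set for a wild-type liver and did not reach the one set against it. The intervals on these shares and on the WT state treat genes of 1 library as independent. They do not measure how far another fish would differ. The absence of an oestrogen response, as in a male or an immature fish, is a candidate explanation, since 2 oestrogen-responsive genes other than the vitellogenins, esr1 and fam20cl, lay below the lowest of the other 5 libraries by log2 ratios of -4.29 and -7.93. The labels give no sex.

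Most cholesterol synthesis genes, 25 of 29 by sign, were higher in mutant libraries. In all 6 libraries edgeR with TMM called 0 of them over all genes, and camera with an estimated correlation did not call the list (adjusted p = 0.960). As the whole cause, the library without vitellogenin is argued against by a list median of 2.85 without it. Ovarian carry-over is argued against in the same sense by 2.39 with the oocyte score as covariate. For vitellogenin's share of the counts, library sizes from the counts outside vitellogenin gave a list median of 2.996 (list mean difference 2.89 ± 0.58, SE). Library sizes move all genes by about the same amount, so this value alone cannot decide on that cause. In that setting the list median stood 2.38 above the median of all genes, and with sizes from all named counts 2.16 above it. Against sizes from all named counts, both without TMM factors, that setting moved the median of all genes from 0.97 to 0.61 and the genes called from 472 to 145 (total counts in the report are those of the filtered genes). The list mean differed by 2.37 ± 0.73, 3.01 ± 0.37 without that library, and 2.41 ± 0.91 with the covariate (SE). Feeding or handling before sampling stays open: 22 measured genes that fasting and glucocorticoids induce had a median of -0.90, on the side set down beforehand for that cause but not called with an estimated correlation (camera, n = 22 genes, p = 0.00350 at the preset correlation and 0.135 with an estimated one), and feeding state cannot be told apart from genotype because the sources used here do not give it. The lost desaturase itself may raise these genes, and that was not tested.

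On in 1 genotype and off in the other were 15 genes (at least 1 CPM in each library of a group, at most 3 counts in each of the other), 10 of them seen in mutant libraries. Counting noise near the floor is argued against by the size of the ratios: each gene had at least 84 counts over 1 group against at most 6 over the other. The exact counting intervals, adjusted over the 23138 genes with a count, had a smallest lower end of 3.07-fold. The genes were chosen by these counts, so this bears on counting error alone, and variation between fish stays open. The bound on the other 9 splits set beforehand was not met, since the highest gave 118 such genes and the next highest 2. The split with 118 sets apart the libraries that carried oocyte transcripts, which the bound did not allow for, and what its genes are was not tested. Linked haplotypes could not be examined, since 53.3% of the genes were matched to the annotation, under the share needed, and 0 of the 8 matched genes had another within 10 genes.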

How the results depend on the processing

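The scd transcript kept its direction and stayed uncalled in 17 of 18 alternatives, as did vitellogenin in 7 of 8 and exocrine pancreas in 4 of 8. Of 989 values for other named genes under an alternative, 824 kept direction and side of the threshold, 121 kept direction and lost the call, 13 kept direction and gained it, and 31 turned. Log2 fold changes that turned were, with total counts, fabp10a 0.59, kdrl 0.56, prss59.1 0.10, fn1b 0.15, zp2.2 -0.37, tfa 0.0328, fga 0.36, b2m 0.85, mt-co1 0.0341, cd74a 0.11 and pla2g12b 0.74. In all 6 libraries with TMM these were, in that order, -0.30, -0.46, -1.12, -0.56, 0.01, -0.61, -0.59, -0.43, -0.74, -1.12 and -0.14. The level of zp2.2 (0.01) also turned with DESeq2 size factors (-0.0142), upper-quartile factors (-0.00321), sizes without vitellogenin and pancreas genes (-0.00485), DESeq2's Wald test (-0.00698), limma-voom (-6.57), without WT replicate 3 (-0.57) and without mutant replicate 1 (-10.44). Without WT replicate 3, b2m was 0.55. Without mutant replicate 1, fads2 (0.26) was -0.78, acadm (0.12) -0.0414, cat (0.20) -0.13 and scd -0.95. Without mutant replicate 3, krt8 (0.51) was -0.47, hbba1 (1.63) -0.43 and vtg1 (-0.29) 0.28. With the oocyte covariate krt8 was -0.0459, and in 5 libraries krt8 was -0.56, hbba1 -0.43 and vtg1 0.25. In leave-one-out the other ends of the ranges were krt8 0.83, hbba1 2.104, fads2 0.73, zp2.2 0.65, b2m -0.82, acadm 0.27, cat 0.41 and vtg1 -1.53. None of these values was called in either fit, and the cause was not tested.

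Genes called, 31 in the analysis above, were 467 with total counts (394 higher, 73 lower), 211 without a filter (94 and 117), 1085 with DESeq2's Wald test (525 and 560), 50 with the oocyte covariate (21 and 29) and 101 with it in 5 libraries (51 and 50), both added after the data were examined. Leave-one-out gave 2 to 77. Of the 20 genes named for size, limma-voom kept 12 and leave-one-out 2 to 18. Lists called, 5 above, were 9 with upper-quartile factors, 11 with total counts, 12 without a filter, 3 with the strict filter, 8 with the covariate, 8 with it in 5 libraries, 0 with an estimated correlation, 8 on ranks and 2 by fry, and 6 to 11 in leave-one-out. The scd change was -0.95 to 3.56 in leave-one-out, the vitellogenin difference -4.93 to 0.25, and that of exocrine pancreas -1.28 to 0.45, with 0.45 and 0.34 without WT replicates 2 and 3 and 0.29 and 0.13 without mutant replicates 1 and 2. The cause was not tested.

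Whether the replicate numbers pair the libraries cannot be told. Deviations from the group mean correlated at 0.298, -0.211 and 0.320 between libraries sharing a number. Mutant replicate 1 correlated at 0.412 with WT replicate 2 and at -0.493 with WT replicate 3. The division by oocyte transcripts enters these values, so they neither show nor exclude pairing. With the number as a block, 2 genes were called, both lower and both among the named 20, and 9 lists, and fads2 turned to -0.11 and zp2.2 to -3.08. Depth limits genes with few counts where vitellogenin leaves 9756360 counts for all others.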

Other observations

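The tests in this part of the 10 splits and of the autophagy list had their outcomes set down before their results were seen, while the other genes named here were chosen after their values were seen. WT replicate 3 stood apart within its own group. The interferon list lay 1.98 above the WT mean in it on the log2 scale, the immediate early list 3.25 above and the myeloid list 1.08 above, against -1.11, -1.80 and -0.63 in WT replicate 1. The binding protein gene igfbp1a was at 2560 CPM there and at 11.3 and 89.0 CPM in the other WT libraries. Mutant replicate 3 shared the higher interferon (1.70) and myeloid (1.502) medians.

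The median of the NADPH supply list deviated from the WT mean by 0.70, 0.53 and 0.62 in mutant replicates 1 to 3. The fatty acid synthase gene fasn was at 501, 344 and 667 CPM in WT and 2200, 1055 and 429 CPM in mutant libraries (edgeR adjusted p = 0.330). The insulin signalling adaptor irs2a was at 19.97, 41.3 and 384 CPM in WT and 0, 1.605 and 2.08 CPM in mutant ones (adjusted p = 0.144).

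The 6 libraries can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. The genotype division called 31 genes and the highest other 242, and 2 of the 10 divisions gave at least 31. The one with 242 set WT replicates 1 and 2 and mutant replicate 1 apart, as oocyte transcripts do, which points to a structure of the samples beside genotype. For the lists at the preset correlation, all 10 divisions called at least 5. The genotype division called 5, the fewest, and the others 9 to 17. A list call at the preset correlation therefore does not by itself set genotype apart from another division. The absolute median of the cholesterol list was 2.52 for genotype and at most 2.07 for another division.

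Because ulk1a was lower, a hypothesis was that autophagy genes are lower more widely. A list of autophagy genes, without ulk1a and the related genes already seen, had a median log2 fold change of -0.02 (camera over the genes, n = 45 genes, p = 0.475), so it neither bears the hypothesis out nor excludes it. Without mutant replicate 3 the median was -0.24 (camera, n = 45 genes, p = 0.0967).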
